A study of Sus scrofa domesticus with 4 samples.

How the data were processed

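RNA from explants of porcine myometrium, the smooth muscle layer of the uterus, was measured on 4 Agilent 2-colour arrays. Per the labels' protocols, the tissue came from 4 gilts on days 15 to 16 of gestation. Slices of about 100 mg and 3 mm thickness were held in 2 ml of medium for 2 h and then cultured for 24 h with adiponectin at 10 µg/ml or without treatment. RNA with an integrity number between 8 and 10 was used, and 825 ng of labelled cRNA per dye was hybridised. Each array held 1 treated and 1 untreated RNA. The labels do not say whether both RNAs of an array came from the same gilt. The gilts are stated to be separate animals, but no label ties an array to an animal, so p-values measure the spread between these 4 arrays, part of which may be technical.

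The dye fields of the labels put treated RNA in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4, and these fields set the direction of every ratio. The text of the labelling protocol describes only treated RNA in Cy5. Per the file headers, arrays 1, 2 and 3 shared slide 1 and scan 1, and array 4 was on slide 2 with scan 2. Both conditions were on every array, so slide and treatment were not confounded.

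The deposited scanner files hold spot and local background intensity per channel, made with Agilent Feature Extraction version 10.7.3.1, per the file headers. They also hold a log10 ratio of Cy5 over Cy3 processed signals, which were background-subtracted and dye-normalised, per the file headers. That ratio was exactly 0 for between 18.1% and 28.9% of the spots of an array. The deposited series table holds log2 ratios with scale, centring and direction not given in the sources used here. Set against the scanner ratios of probes well above background in both channels, its slopes were 1.00, -1.00, 1.00 and -1.00 on arrays 1 to 4, and at least 99.99% of the values lay within 0.01 once the signs of arrays 2 and 4 were turned. Its column medians were -0.10, 0.13, -0.14 and 0.16. For probes well above background its scale and direction were thus settled as log2 of treated over control with no further centring. How values of dim probes were made stays unknown.

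Median spot intensity was used because the files hold no mean signal, which the plan had named. Intensity was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3. Loess normalisation followed within each array, with control and outlier-marked spots at weight 0. On each array 1417 spots were controls and 43803 carried 43603 probes, 50 of them spotted more than once. Spots of a probe were averaged. A probe was tested when its spot was well above background on at least 3 of 4 arrays in the treated or in the control channel and when no array lacked a value. This left 22133 probes (50.8%), after 159 bright enough probes were dropped for a missing value.

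RefSeq accessions, without versions, were matched to a table of assembly Sscrofa11.1, which was used for names only. Of 7125 probes with a RefSeq accession, 6700 received 1 of 3029 symbols. The other 36903 probes stayed unnamed here and were tested as probes. The tested probes covered 2134 named genes. The probe with the highest mean signal stood for a gene, and 1055 genes had more than 1 tested probe. No coordinates are given because the array files name no genome build.

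Ratios were fitted with limma (lmFit and eBayes) with a treatment coefficient and a probe-specific dye coefficient, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Intervals are 95% intervals of the moderated coefficient. Values after ± are its moderated SE, which leaves out the spread of array values that the dye coefficient takes up. Ratios and list medians given for single arrays still hold the dye offset of each probe. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on 1 probe per gene, adjusted over the lists tested. An estimated correlation and fry were the alternatives. The 32 lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined. Lists with fewer than 5 tested genes were not tested. The rule took, per direction, 12 genes with the largest change among those past the threshold and of the same sign on all 4 arrays. Free places were filled with the smallest unadjusted p among genes of the same sign on all 4 arrays. It added members of each list that passed when adjusted over the list alone, up to 4, or otherwise the 2 with the smallest unadjusted p, and 8 genes of adiponectin and uterine hormone biology. Of the genes it gave, 81 are reported, and a result it also named is not reported here.

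The fit was tested on simulated data, in 20 simulations of 22133 probes with 200 changed. With the spread drawn from the prior that limma fitted, 2.1% of changes of 0.5 on the log2 scale were recovered, 71.7% of changes of 1, 94.6% of 1.5 and 97.7% of 2, and 5.07% of the calls were false. With each probe's own shrunken spread, the recovered shares were 34.8%, 99%, 99.5% and 100%, and 9.85% of the calls were false. For a list of 11 genes, camera with the preset correlation called 4 of 100 simulated lists with no change and 100 of 100 shifted by 0.5. It also called 49 of 100 unshifted lists whose members shared a random component with an SD of 0.5 on each array. With an estimated correlation, 0 of 100 lists were called in each of these settings, the shifted one included. Fry was not simulated.

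Alternatives covered the dye term, the dye orientation, background correction, normalisation within and between arrays, the scanner ratio, the series table, the filter on dim probes, the array as a block, the variance model, array weights, slide, threshold, set test, the choice of probe and leaving out each array. Slide as a random block was not run because no correlation could be estimated with 1 array on slide 2. Fits with 1 array left out kept the dye term. In them, the array left alone in its dye orientation weighed as much as the others together.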

Results

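The series asked how adiponectin, a hormone secreted mainly by fat tissue, affects gene expression in the myometrium of early pregnant pigs. The 4 arrays each compared an adiponectin-treated explant culture with an untreated one after 24 h. In Cy3, between 46.1% and 51.0% of the spots were well above background, and in Cy5 between 54.9% and 63.1%. The number of arrays limited the precision: the median 95% interval of a probe reached 0.25 on the log2 scale to either side, a fold of 1.19.

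No named gene passed the test for a change with adiponectin. EMP1, of the epithelial membrane protein family, had similar values on the 4 arrays, with a log2 change of 0.62 ± 0.09 (SE, n = 4 arrays), a 1.54-fold higher signal, and array values of 0.68, 0.59, 0.51 and 0.70. KLF6, a zinc finger transcription factor, stood at 0.72 ± 0.16 and RND3 at 0.63 ± 0.12. On the lower side, PSMB8, a subunit of the immunoproteasome, stood at -0.44 ± 0.10 and GPR1, a receptor for the adipokine chemerin, at -0.39 ± 0.09. The limma adjusted p was 0.959 for each of these 5 genes.

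Across the 22133 probes, limma called 0 higher and 0 lower, and the smallest adjusted p was 0.959. At an unadjusted p under 0.05 it counted 759 higher and 375 lower probes, 5.12% of those tested, where chance alone gives about 1107 probes. With median centring in place of loess, that split was 222 higher and 2251 lower. Of the 2134 named genes, 245 (11.5%) had the same sign on all 4 arrays. Chance gives 12.5% for ratios without a dye offset and less with one, so this share does not test for a shared response.

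The other genes placed highest by the naming rule had positive values on all 4 arrays and did not pass. UTP3 was at 0.54, RSAD2, an interferon-induced antiviral protein, at 0.59, and PPP4R3B at 0.55. CPT1A, which carries long-chain fatty acids into mitochondrial oxidation, was at 0.50, DDX46, an RNA helicase, at 0.47, and MUC4, a membrane mucin, at 0.42. SECISBP2L was at 0.41, and FCGRT, the neonatal Fc receptor, and ABCF1 were both at 0.39. Values below 0 on all 4 arrays were found for RPL13A, a ribosomal protein (-0.39), HMGA1, a chromatin protein (-0.37), and FUBP3 (-0.35). ZFAND5 was at -0.34, PDIA4, a protein disulfide isomerase of the endoplasmic reticulum, at -0.33, and FBXO32 and METTL9 both at -0.33. ACKR1 was at -0.32, CCS, the copper chaperone of superoxide dismutase 1, at -0.31, and DNAJA4 at -0.29. Among the 48 named genes with several tested probes, the probes differed in sign for 8: UTP3, ABCF1, FCGRT, SMAD4, TNC, CASP8, WT1 and CDH13. Other genes had probes of the same sign but unlike size. They spanned 0.09 to 0.72 for KLF6, 0.23 to 0.59 for RSAD2, 0.19 to 0.50 for CPT1A and -0.37 to -0.03 for HMGA1. For VSIG4 they spanned 0.17 to 0.83, for CD163 0.46 to 0.87 and for DNAJB1 -0.54 to -0.09. In these the reported probe lay farthest from 0, and for FBXO32 (-0.68 to -0.33) and MMP9 (0.86 to 1.13) it lay nearest.

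**Figure D1:**
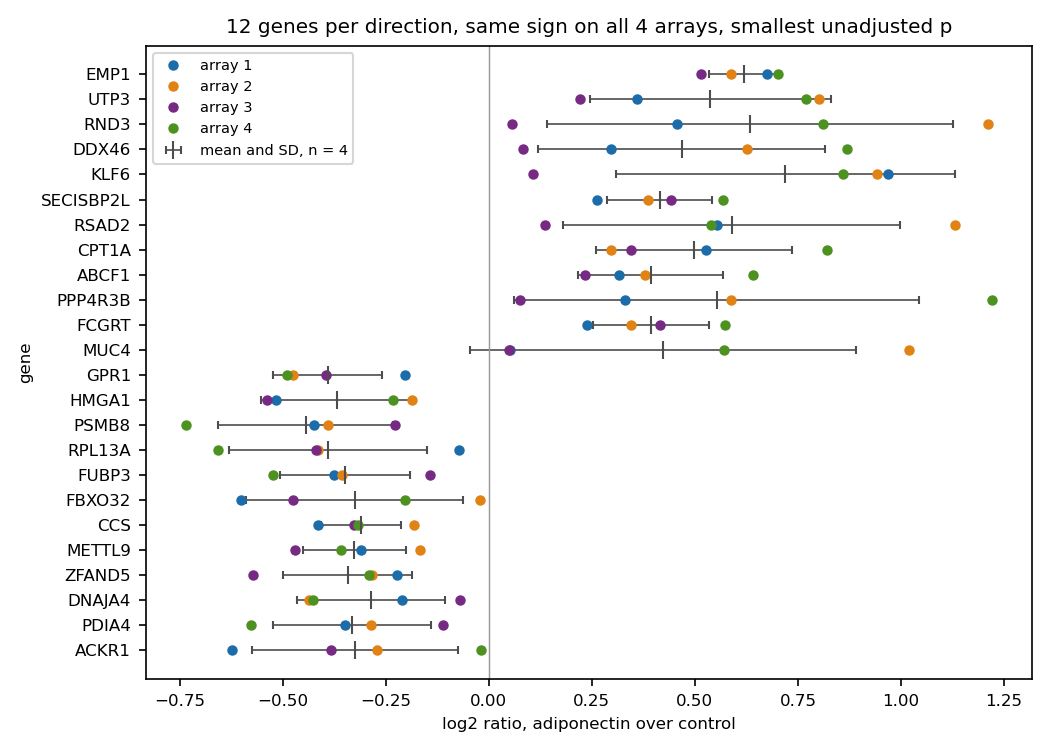
Log2 ratios of adiponectin over control (x axis) for the 12 genes per direction with the smallest unadjusted p among those of the same sign on all 4 arrays (y axis), with 1 point per array and the mean with its SD over 4 arrays. The points of EMP1 lie between 0.51 and 0.70, while those of RND3 spread from 0.06 to 1.21.

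Markers of macrophages and monocytes rose as a list, with a median log2 change of 0.56 over 11 tested genes, 10 of them above 0 (camera adjusted p = 2.7e-05 with the preset correlation, 0.948 with an estimated correlation and 0.943 with fry). In simulations of this design, the preset setting also called 49 of 100 unshifted lists whose members shared a component, and the correlation estimated for this list was 0.96. The estimated setting recovered no shifted list in the simulations, and fry was not simulated. CD163, a scavenger receptor of macrophages, was at 0.87 ± 0.26 and VSIG4, a complement receptor of tissue macrophages, at 0.83 ± 0.25. No member passed on its own, over all genes or adjusted over the list alone. The list median was 0.26, -0.16, 1.65 and 0.63 on arrays 1 to 4. On array 3 the medians of other lists also lay far from 0, at -0.47 for endometrial epithelium, 0.53 for smooth muscle genes and -0.66 for hypoxia and glycolysis. It was 0.21 without array 3, 0.30 without array 4, 0.90 without array 1 and 0.81 without array 2, and the array 4 omission leaves slide 1 alone. CD14 was at -0.01.

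**Figure D2:**
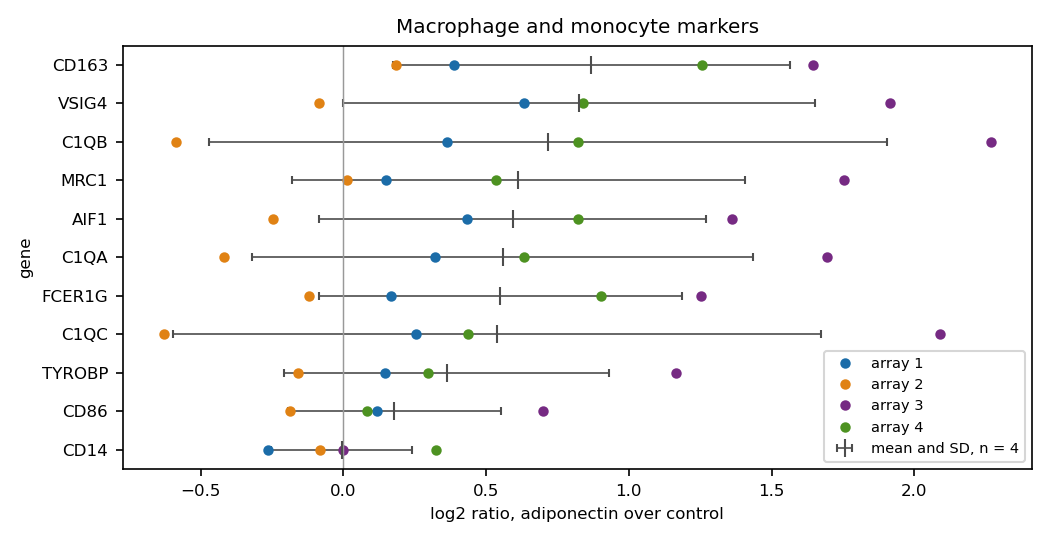
Log2 ratios of adiponectin over control (x axis) for the 11 tested macrophage and monocyte markers (y axis), with 1 point per array and the mean with its SD over 4 arrays. Array 3 holds the highest value of 10 markers, and CD14 is the exception.

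Of the 28 lists tested, this was the 1 list past the threshold with the preset correlation. With an estimated correlation the smallest adjusted p over the lists was 0.948. That setting called no shifted list in the simulations, so its values here and below cannot count against a list. With fry, 0 lists passed by direction (smallest adjusted p = 0.843) and 0 by change in either direction (0.129). Fry was not simulated, so whether it could call a shifted list here is unknown. Over all genes, 0 of the 405 tested list genes passed. When adjusted over the list alone, 1 passed: GPR1 among the adipokines and their receptors (adjusted p = 0.0375), with no adjustment for the number of lists. The other tested probe of GPR1 was at -0.19. For adiponectin receptors and AMPK signalling, extracellular matrix structure, immediate early genes and endothelium markers, the list median and the direction of the camera test differed in sign, with medians near 0.

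Genes of adiponectin action did not pass as a list. The median of the 16 tested genes of adiponectin receptors and AMPK signalling was -0.01 (camera adjusted p = 0.841). The receptor ADIPOR1 was at -0.24 ± 0.13, ADIPOR2 at 0.07 ± 0.10 and the adiponectin-binding cadherin CDH13 at -0.02 ± 0.09. PRKAB2, a regulatory subunit of AMPK, was at 0.34. ADIPOQ, the gene of adiponectin itself, was not tested because its probes were well above background on at most 2 arrays. The adipokines and their receptors had a median of -0.23 with 6 of 7 genes below 0 (camera adjusted p = 0.0765). They passed without the dye term (adjusted p = 0.0461) and without array 1 or array 2 (0.00586 and 0.0163). They did not pass without array 3 (median -0.15, 0.178) or array 4 (-0.18, 0.333). The median was -0.04 without the filter on dim probes (0.298), and the adjusted p was 0.948 with an estimated correlation and 0.843 with fry.

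Lipid and steroid metabolism gave no list past the threshold. Cholesterol and fatty acid synthesis had a median of -0.09 with 12 of 16 genes below 0 (adjusted p = 0.0790), FDPS at -0.32 and INSIG1 at -0.29. It passed when all probes of a gene were averaged (adjusted p = 0.0140) and without array 1 (0.00809), and not without array 3 (median -0.06, 0.582), with an estimated correlation (0.948) or with fry (0.843). Fatty acid uptake and oxidation stood at -0.02 (adjusted p = 0.890), with FABP5, a fatty acid binding protein, at 0.78 ± 0.22. Steroid synthesis and conversion stood at -0.04 (0.762), with HSD17B4 at -0.21 and SULT2A1 at -0.35, the latter well above background on 2 of 4 arrays in the treated channel. Adipocyte markers stood at -0.11 (0.346), with PNPLA2 at -0.22 and LIPE at -0.14. Oxidative phosphorylation stood at 0.02 (0.841), with NDUFA4 at 0.18 and COX7A2 at 0.14.

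Genes of uterine contraction and hormone response also gave no call over all 4 arrays. Hormone receptors and contraction-associated genes had a median of 0.09 with 16 of 24 genes above 0 (adjusted p = 0.214), and of 0.04 without array 4. The oxytocin receptor OXTR was at 0.35 ± 0.12, with array values of 0.41, -0.09, 0.84 and 0.23. PGR was at 0.00 and ESR1 at -0.03. PTGS2, the inducible cyclooxygenase, was at 0.04 ± 0.45, with 1.47 on array 1 and -1.46 on array 3. Prostaglandin synthesis and receptors had a median of -0.09 (0.782), with AKR1CL1 at -0.34 and TBXAS1 at 0.24. Each of these 2 genes was well above background on only part of the arrays, AKR1CL1 on 3 in either condition and TBXAS1 on 4 in the treated and 2 in the control channel. The smooth muscle contractile apparatus had a median of 0.01 (0.841), with VCL at 0.25 and MYL9 at -0.14. It passed with the preset correlation in opposite directions without array 1 (0.16, 0.000744) and without array 3 (-0.21, 0.0141), and over all 4 arrays the adjusted p was 0.948 with an estimated correlation.

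Matrix and growth factor lists gave no call over all 4 arrays. TGF-beta and BMP signalling had a median of 0.10 with 15 of 19 genes above 0 (adjusted p = 0.0790), SMAD4 at 0.33 and FST at 0.22, though another SMAD4 probe stood at -0.19. The list median was 0.04 without array 1 and 0.12 without array 3, where the list passed with the preset correlation (0.0160). Matrix proteases and inhibitors stood at 0.15 (0.241), with MMP9 at 0.86 ± 0.27 and CTSK at -0.26, and at 0.01 without array 4 and 0.27 without array 2, where they passed with the preset correlation (0.0116). With an estimated correlation over all 4 arrays, the adjusted p of both lists was 0.948. Extracellular matrix structure stood at 0.01 (0.919), with TNC at -0.37 and THBS1 at 0.30. Angiogenesis and growth factors stood at 0.00 (0.841), with IGFBP6 at -0.33 and IGF2 at -0.26.

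Inflammatory and stress lists did not pass over all 4 arrays either. Cytokines and chemokines had a median of 0.03 (adjusted p = 0.782), with the neutrophil attractant CXCL8 at 0.84 ± 0.25 and CXCL12 at -0.31. Array by array, CXCL8 stood at 0.25, 0.32, 1.46 and 1.31. MMP9 (0.30, 0.22, 1.6 and 1.32), FABP5 (0.51, 0.09, 1.5 and 1.05) and CD163 (0.39, 0.19, 1.65 and 1.25) were likewise highest on arrays 3 and 4. This likeness was seen afterwards, and these need not be separate results. NF-kappaB targets stood at -0.01 (0.833), with VCAM1 at -0.47 and TLR2 at 0.23. The interferon response stood at -0.09 (0.840), and its members RSAD2 and PSMB8 had opposite signs. Hypoxia and glycolysis stood at -0.07 (0.782), with PDK1 at -0.32 and TPI1 at -0.20. The unfolded protein and heat shock response stood at -0.02 (0.841), with DNAJB1 at -0.54. The antioxidant response stood at -0.05 (0.782), with FTH1 at 0.38 and KEAP1 at -0.15. Immediate early genes stood at -0.01 (0.782), with BTG2 at -0.29. Apoptosis stood at 0.10 (0.241), with BCL2A1 at 0.48 and CASP8 at 0.27, and its median was -0.01 when all probes of a gene were averaged. Without array 1, 3 of these lists passed with the preset correlation: cytokines and chemokines (0.14, adjusted p = 0.0302), the interferon response (-0.13, 0.0237) and hypoxia and glycolysis (-0.35, 3.5e-08). Without array 3, 2 passed, hypoxia and glycolysis (0.17, 0.000807) and immediate early genes (0.16, 0.0282), while the interferon response stood at 0.04 and cytokines at -0.06. With an estimated correlation over all 4 arrays, the adjusted p of each of these 4 lists was 0.948.

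Markers of other cell types gave medians of 0.00 for endothelium (adjusted p = 0.841), with ENG at -0.33 and PECAM1 at 0.28. They were 0.01 for lymphocytes (0.782), with NKG7 at 0.13, and -0.05 for neutrophils (0.782), with FCGR3A at 0.57 and PGLYRP1 at -0.16. Array by array, FCGR3A stood at 0.43, -0.53, 1.89 and 0.50, the same signs as the macrophage list median, and at 0.21 without array 3. IL7R was not well above background in the control channel on any array, and was so on 3 arrays in the treated channel. Its log2 change was 0.43, with an interval from -0.005 to 0.87 that includes no change (limma adjusted p = 0.959). Its array values were 0.23, -0.01, 1.21 and 0.29, and the log2 change was 0.19 without array 3. The mean of its normalised treated signals over all 4 arrays was 1.27-fold above a floor for the control signal. That floor was the higher of the lowest bright signal and the probe's own signal on each array. It does not cap the true control signal of a dim spot, so 1.27 is not a lower limit of the change. Connective tissue stroma stood at -0.10 (0.782), with SFRP4 at -0.30 and ASPN at 0.23, and its median was -0.03 without array 3. Endometrial epithelium stood at 0.11 (0.434), with KRT8 at 0.21. The epithelial median was 0.01 without array 1, -0.08 without array 2, 0.21 without array 3 (adjusted p = 0.0461) and 0.25 without array 4 (0.00215), and over all 4 arrays the adjusted p was 0.948 with an estimated correlation (0.54) and 0.943 with fry. Below the minimum of 5 tested genes were cell cycle with 4 (CCND2 at 0.25, CDK1 at 0.17), pericytes with 3 (RGS5 at 0.55, RGS4 at 0.37, and 0.11 and 0.07 without array 2), mesothelium with 1 (WT1 at 0.09) and erythrocytes with 0.

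Leaving out 1 array changed many of these values. In these fits the array left alone in its dye orientation weighed as much as the others together. That was array 3 without array 1, array 1 without array 3, array 4 without array 2 and array 2 without array 4. A change thus reflects the added weight of that array as well as the omission. Of the 81 named genes, 11 changed sign in at least 1 omission: AKR1CL1, MYL9, PDK1, NKG7, WT1, PNPLA2, ADIPOR2, CDH13, PTGS2, PGR and ESR1. In 35 more, at least 1 omission brought the log2 change toward 0 by over 1.5 times, among them IL7R, FCGR3A, RGS5 and RGS4. Without array 3 the log2 changes were PRKAB2 0.22, SULT2A1 -0.15, VCL 0.02, MMP9 0.54, CXCL8 0.54, TPI1 -0.05, DNAJB1 -0.26 and BTG2 -0.02, and also CDK1 0.01, BCL2A1 0.30, NDUFA4 0.09, CD163 0.55, VSIG4 0.50, PGLYRP1 -0.09, SFRP4 -0.10 and LIPE -0.03. Without array 1 they were CTSK -0.10, FST 0.10, KEAP1 -0.08, CASP8 0.14 and KRT8 0.08, without array 2 ADIPOR1 -0.08, TBXAS1 0.12, IGF2 -0.14 and ENG -0.21, and without array 4 HSD17B4 -0.06, THBS1 0.18, VCAM1 -0.27, CCND2 0.15, COX7A2 0.01 and PECAM1 0.14. The other 35 genes, which include the 12 per direction with the smallest unadjusted p, did neither. Those 12 per direction were picked for the same sign on all 4 arrays, so no omission could turn them. A small p also favours a small spread, so their stability says nothing about a response. Of the 28 list medians, 15 changed sign between omissions, most of them near 0 over all 4 arrays, and 11 lists passed in at least 1 omission with the preset correlation, where the estimated one was not run.

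**Figure D3:**
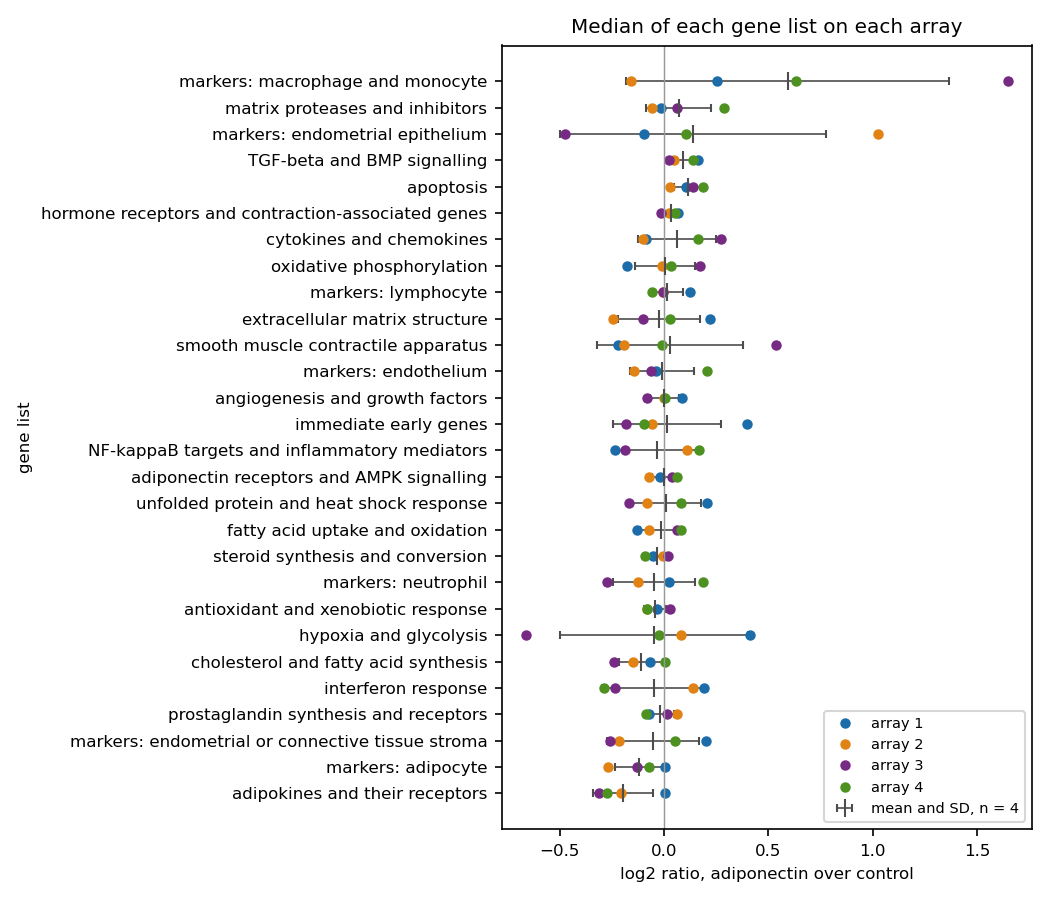
Median log2 ratio of adiponectin over control (x axis) of each of the 28 tested gene lists (y axis) on each array, with the mean and SD of the 4 array medians. The macrophage list spreads from -0.16 to 1.65 and hypoxia and glycolysis from -0.66 to 0.41.

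The log ratios of the arrays were compared over the tested probes to see whether the dye orientation in the labels gave similar responses. With the signs turned by the labels, Pearson's r between pairs of arrays lay between -0.27 (arrays 2 and 3) and 0.21 (arrays 2 and 4), with a mean of -0.02. Before turning, the mean was 0.05. These are correlations across probes, which are not independent replicates. The turned ratios still hold each probe's dye offset, which sets arrays 1 and 3 against arrays 2 and 4. RND3, for example, stood at 0.46 and 0.06 on arrays 1 and 3 and at 1.21 and 0.81 on arrays 2 and 4. MUC4 stood at 0.05 and 0.05 against 1.02 and 0.57. The fit assigns such a split to the dye coefficient, so these 2 genes do not show unlike responses.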

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

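The tests of explanations below were chosen after the results were seen, except the comparison of probes of the same gene.

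In 2 of 109 sets of 4 array values, 1 array lay far from the other 3, where chance gives about 5.45. KLF6 was at 0.11 on array 3 and between 0.86 and 0.97 on the others. COX7A2, a subunit of cytochrome c oxidase, was at 0.58 on array 4 and between -0.05 and 0.04 on the others.

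The macrophage and monocyte markers were higher after adiponectin as a list, by 0.56, a call made with camera at the preset correlation. It was not made with fry (adjusted p = 0.943) or with an estimated correlation (0.948). The latter setting called 0 of 100 shifted lists in the simulations, so its value decides nothing here. Fry was not run on simulated lists, so whether it could call such a shift is unknown. A lower share of smooth muscle in the treated explants would raise markers of the other cell types alike. The median of 22 markers of endothelium, lymphocytes, neutrophils and connective tissue was 0.06, -0.15, -0.17 and 0.05 on arrays 1 to 4, and the macrophage median lay above it by 0.20, -0.02, 1.82 and 0.58. On array 3, which had the highest list median, the 95% bootstrap interval over genes was 1.17 to 1.92 for the macrophage markers and -0.28 to 0.01 for the other cell types, a gap of 1.82 between the medians. All 12 smooth muscle genes were higher there (median 0.53, interval 0.35 to 0.89), which argues against a lower muscle share on that array. These intervals resample genes that moved together on 1 array, picked for its high median. They do not measure the spread between cultures. Over all 4 arrays the mean gap was 0.65, with a 95% interval from -0.66 to 1.95. On the other 3 arrays the mean gap of 0.256 had a 95% interval from -0.50 to 1.01, so the explanation stays open for them. Members of the macrophage list moved together from array to array, with an inter-gene correlation of 0.96 in camera, estimated with 2 residual degrees of freedom. The median over the lists was 0.08, but some other lists were also high. Smooth muscle genes had 0.785, endometrial epithelium 0.54 and hypoxia and glycolysis 0.497. Macrophage content that differed between the explants compared would give such a correlation, so uneven content may have shaped the shift. A programme shared by macrophage genes would give the same correlation. An effect of adiponectin in every culture stays open, since an exact sign-flip test of the 4 list medians gave p = 0.25 and cannot go below 0.125. All 11 members were detected in the control channel on at least 3 arrays and 1 member belongs to another list.

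The ratios of the 4 arrays did not correlate. Noise of single spots alone would leave probes of the same gene unrelated, but over 1055 genes the correlation between 2 probes was 0.76, 0.74, 0.79 and 0.47 on arrays 1 to 4, at least 0.469. Repeat spots of 24 probes gave 0.56, 0.35, 0.32 and 0.57, lower on 3 of the 4 arrays, and the cause was not tested. Probes of a gene on an array read the same labelled RNAs, so this comparison cannot detect error that they share. A wrong dye label on 1 or more arrays would leave another assignment of signs with a clear correlation, but the highest mean among 8 assignments was 0.104, which argues against a strong shared response hidden by labels and not against a weak one. Differences between the explants or animals of each array may remain, as may error shared by the probes of an array and a small response common to all. None of these was tested.

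The 3 balanced assignments of dye signs are too few for a share under 0.05. All 3 gave 0 called probes at the adjusted threshold, the highest other being 0. For gene lists, 3 of the 3 gave at least the 1 list of the labelled assignment, the highest other being 6, in the assignment that joins arrays 1 and 4. For the macrophage list, 1 of 3 shifted the median as far as the labelled 0.56, the labelled one itself, and the farthest other was -0.53. That other assignment, which joins arrays 1 and 4, gave the list an unadjusted camera p of 6.7e-05, against 9.6e-07 for the labelled one. A small camera p for this list thus also arose under signs that the labels do not give. At an unadjusted p under 0.05, the labelled assignment gave 1134 probes, the one that joins arrays 1 and 4 gave 1762 and the remaining one 572.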

How the results depend on the processing

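Counts of called probes stayed at 0 higher and 0 lower under each alternative fit at an adjusted p under 0.05, leaving out each array included, and at 0.10. The smallest adjusted p of any fit was 0.0554, without array 2. Aquantile left the ratios as they were, by construction. At an unadjusted p under 0.05 with a fold of at least 1.2, 635 probes were higher and 264 lower. The count of gene lists past the threshold was 1, and 0 with an estimated correlation or with fry, 2 without the dye term, 2 with all probes of a gene averaged, and between 2 and 7 when 1 array was left out. The macrophage list had an adjusted p of 0.948 with an estimated correlation and 0.943 with fry, which change the test and not the median of 0.56. The median lay between 0.21 and 0.90 (adjusted p from 9.7e-09 to 0.0461) when 1 array was left out. Except with the estimated correlation, where the simulations show a test that made no calls at this size, the cause was not tested. The mean correlation between arrays was 0.00 with the scanner ratio. With the dye mean removed it was 0.102, the value that unrelated simulated arrays give (0.102), so that setting says nothing about stability. With the 8 channels as separate samples (no replicate block), 0 probes were higher and 0 lower. Signal over background limits the dim probes: the scanner ratio was exactly 0 for 47.4% to 64.3% of the spots bright in neither channel and for 0% of those bright in both. No named gene had an adjusted p under 0.05 in any fit (smallest 0.262), while 43 of 81 met an unadjusted p under 0.05 with a fold of at least 1.2. Apart from the genes of adiponectin and uterine hormone biology, the naming rule picked genes for a small unadjusted p. That selection raises the count of 43, so the count does not test for a response. Among all 22133 tested probes, the same criterion was met by the 635 higher and 264 lower probes given above. Of 1450 values of named genes under alternatives, 70 changed sign, in 50 genes, and the cause was not tested beyond the sign turned on arrays 2 and 4.

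Reading treated RNA as Cy5 on all arrays gave log2 changes of EMP1 -0.0254, UTP3 -0.25, RND3 -0.38, DDX46 -0.28, KLF6 -0.18, SECISBP2L -0.062, RSAD2 -0.24, CPT1A -0.0607 and ABCF1 -0.12. That reading also gave PPP4R3B -0.35, FCGRT -0.0663, MUC4 -0.37, GPR1 0.0911, PSMB8 0.12, RPL13A 0.14, FUBP3 0.0904, DNAJA4 0.15 and PDIA4 0.10. It further gave PRKAB2 -0.0079, ADIPOR1 0.0927, INSIG1 0.0882, SULT2A1 0.0675, TBXAS1 -0.0987, VCL -0.00426, MYL9 0.44, TNC 0.34 and IGFBP6 0.36. The same setting gave IGF2 0.0639, KEAP1 0.0103, CASP8 -0.13, NDUFA4 -0.17, COX7A2 -0.16, PECAM1 -0.14, PGLYRP1 0.0163, KRT8 -0.36 and ASPN -0.0378. Last, it gave SFRP4 0.20, PNPLA2 0.0727, LIPE 0.0341, RGS5 -0.32, RGS4 -0.51, PTGS2 -0.0377 and PGR 0.33. With median centring, values were VCL -0.00997, NDUFA4 -0.089, COX7A2 -0.12, WT1 -0.0758 and PTGS2 -0.19. On slide 1 alone, they were ADIPOR2 -0.00964, PTGS2 -0.0596 and PGR 0.0499. Without background correction, they were PGR 0.0013 and ESR1 0.00591. With the scanner ratio, they were PGR 0.00225 and ESR1 0.025. With the series table, they were PGR 0.00225 and ESR1 0.025. Leaving out 1 array moved AKR1CL1 from -0.71 to 0.034, MYL9 from -0.31 to 0.0193, PDK1 from -0.69 to 0.0475, NKG7 from -0.0333 to 0.28, WT1 from -0.23 to 0.41. It moved PNPLA2 from -0.44 to 0.00708, ADIPOR2 from -0.00964 to 0.14, CDH13 from -0.0842 to 0.0355, PTGS2 from -0.69 to 0.77, PGR from -0.10 to 0.093 and ESR1 from -0.14 to 0.0723.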

Other observations

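The comparisons of single arrays below were chosen after the results were seen. Single-array ratios still hold each probe's dye offset, so they are not differences between explants alone. At an unadjusted limma p under 0.05, 1475 probes had a dye effect and 1134 a treatment effect. When adjusted, 0 probes had a dye effect. The ratios of several gene lists changed from array to array. On array 3, 15 of 17 hypoxia and glycolysis genes were lower in the treated explant (median -0.66), with DDIT4, an mTOR inhibitor induced by stress, at -2.42, P4HA1, a collagen prolyl hydroxylase, at -1.89 and VEGFA at -1.59. On array 1, 15 of the 17 were higher (median 0.41), with DDIT4 at 1.01 and VEGFA at 0.74. All 12 smooth muscle genes were higher on array 3 (median 0.53), ACTA2 at 1.67 and DES at 1.27, and on array 1 their median was -0.22. Arrays 1 and 3 share a dye orientation, so a dye offset alone would not give these 2 lists opposite signs there. Epithelial markers had higher ratios on array 2, with 9 of 9 above 0 (median 1.02, EPCAM at 1.16 and CDH1 at 1.24), and 8 of 9 were below 0 on array 3 (median -0.47). Their medians on arrays 1 and 4 were -0.10 and 0.10, so the sign followed the dye orientation. A dye offset may be part of the epithelial values, which was not tested. DDIT4, P4HA1, VEGFA, ACTA2, DES, EPCAM and CDH1 were named after their values were seen.

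Medians were set against 10000 random lists of the same size matched on mean signal, and 11 of 112 pairs of list and array had medians that fewer than 10 random lists matched. Random lists hold unrelated genes, so related genes pass this bar more often with no treatment effect, and the percentiles only describe single arrays. The interferon response was among them on array 3 (median -0.23) and array 4 (median -0.29), with the interferon-induced chemokines CXCL9 at -2.47 and CXCL10 at -1.41 on array 3. Both chemokines were above 0 on arrays 1 and 2, and were named after their values were seen. The immediate early genes stood out on array 1 (median 0.40) and the cytokines and chemokines on array 3 (median 0.27).

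With 1 array left out, some list medians turned, in fits where the array left alone in its dye orientation weighed most. Hypoxia and glycolysis had a median of -0.35 without array 1 and 0.17 without array 3, and smooth muscle genes had 0.16 without array 1 and -0.21 without array 3. All 4 values passed camera with the preset correlation, a setting that also called 49 of 100 simulated unshifted lists whose members shared a component. Over all 4 arrays neither list passed, and the adjusted p with an estimated correlation, which called no shifted list in the simulations, was 0.948 for both. That correlation was not estimated with an array left out.

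UABP-2, a gene of the epithelial list, was at -3.66 on array 4 and 1.05 on array 2, and was named after its values were seen.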
